A study of Mus musculus with 47 samples.

How the data were processed

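RNA was measured in cranial neural crest cells of mouse embryos, the cells that leave the neural folds and build most of the facial skeleton. Per the labels' protocols, cells were dissociated with trypsin and sorted by fluorescence, total RNA was purified with a PicoPure kit, and libraries were made with ScriptSeq v2. Libraries were read as single ends of 50 bases on a HiSeq instrument, with 3 barcoded samples per pool, per the labels' protocols. The table used here comes from 47 libraries in 16 groups of stage, subpopulation and genotype. The labels number the replicates of each group but do not say whether each is a separate embryo or litter, so p-values measure the spread between these samples. That spread is estimated for each gene over all groups together, so it can differ from the spread within the groups compared.

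The deposited values are raw read counts per gene, per the file headers and the labels' processing notes. The authors demultiplexed with bcl2fastq 2.17 and used the assembly GRCm38, also named mm10, per the labels' protocols. The aligner, the counting tool and the annotation release are not given in the sources used here. The table holds 38215 genes with an identifier, a symbol and coordinates, and all values checked were whole numbers. In the table, 22 column names appear 2 times, and all 22 repeats hold identical values, so each was used once. No column belonged to a sample outside the labels. Symbols were shared by 2 or more identifiers for 4004 genes, so genes were followed by identifier. It is not stated that the counting used strand, so counts of an antisense transcript such as Hoxb3os, Dlx6as1 or Dnm3os and of the gene it overlaps are uncertain. Paralogs and multigene families, such as the globins, the 7SK copies and Hspa1a with Hspa1b, are uncertain for the same kind of reason.

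Totals ran from 18.8 to 49.8 M counts (M for 1e6) per library with a median of 30.6 M. The 3 counts used as a floor, over a group, set the lowest level that a count of 0 allows, and such floors and counting intervals cover counting error only. Mitochondrial ribosomal RNA took 21.6% of all counts. Between libraries of a group, chi-square per degree of freedom over genes with at least 20 counts per pair ran from 3.38 to 121, where 1 is counting noise alone. TMM factors ran from 0.514 to 1.16.

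Counts were fitted with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 20560 genes. All 47 libraries entered 1 model with a mean per group, TMM scaling and a shared estimate of the spread on 31 residual degrees of freedom. Each comparison was tested with edgeR's quasi-likelihood test. Adjusted p-values are from that test with Benjamini-Hochberg adjustment within a comparison, and a gene was called higher or lower at an adjusted p under 0.05. Errors of log2 fold changes are standard errors taken from the F statistic. Levels are counts per 1e6 counts of the TMM-scaled library total (CPM), as mean ± SD over libraries. For a gene at 0 counts on one side, a lower bound of the fold is given against 3 counts over that group. With 1 to 3 counts, the ratio is given with its 95% counting interval.

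At E10.5 and at E11.5, each wild-type subpopulation was compared with the mean of the log2 levels of the other 3. A gene near 0 in one of those 3 can therefore show a high fold beside a similar mean CPM. PA2 was compared with Md at both stages, E10.5 with E8.5, and E11.5 with E10.5. Ezh2cKO was compared with wild type in each subpopulation and averaged over the 4, and an F test of 3 contrasts asked whether the effect differed between them. HoxA2OE was compared with wild-type Md, Hoxa2TempMut with Control PA2, and Control with wild-type PA2. The model, the comparisons, the lists and the naming rule were fixed before the data were examined.

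Named genes are the targeted gene and, among called genes with at least 5 CPM on the higher side, a named symbol and no overlap between the libraries of both sides, those of largest fold. For averages over subpopulations, the same sign in each replaced the condition on overlap. For a gene list, up to 4 called members of largest fold were named, with Hoxa2, Ezh2, Cdkn2a, Alx1 and Hand2 where they belong to it.

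Members of 24 gene lists written from general knowledge were tested. The positional lists were anterior Hox, posterior Hox, frontonasal regulators, maxillary and proximal arch regulators, distal arch regulators, candidate Hoxa2-activated genes and candidate Hoxa2-repressed genes of the first arch. The regulatory lists were early neural crest specification, components of the Polycomb complexes PRC2 and canonical PRC1, cell-cycle inhibitors, p53 targets, regulators of other lineages, neural regulators, cartilage and bone, hedgehog targets and proliferation. The cell-type and stress lists were neuron and glia, epithelium, endothelium, erythroid, leukocyte, cranial mesoderm and muscle, and immediate early response. Some genes are in more than 1 list. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, again with an estimated correlation, and with fry. Where a call ended with the estimated correlation, that adjusted p is printed beside it, and otherwise the call held. Further lists of sensory ganglion and skeletal muscle genes served the closing section. List genes that did not pass the filter, among them Cdx2, Pdx1, Evx1, Evx2, Olig1, Krt14, Hba-a1, Hba-a2, Tyrobp, C1qa, C1qb and C1qc, were left out.

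Positional sets were the genes called in a subpopulation at E11.5 with a log2 fold change of at least 1 and every library above those of the other 3. They were tested in Ezh2cKO at E10.5, so that set and test shared no library. For the same reason, genes higher in PA2 than in Md, and the reverse, were taken from E11.5 for HoxA2OE and from E10.5 for Hoxa2TempMut. Overlaps of called genes were tested with Fisher's exact test, 2-sided.

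The scripts were tested on simulated counts with 20263 genes. At a 1.5-fold change, 64.2% of changed genes were recovered in the Ezh2cKO comparison of PA2, 70.1% for HoxA2OE, 68.7% for Hoxa2TempMut and 86.6% for PA2 at E11.5. At a 4-fold change, 100% were recovered in each. Unchanged genes made up 6.91%, 3.24%, 3.76% and 4.02% of the calls in that order. Each simulated gene had the same spread in all groups, and the few changed genes started from at least 5 CPM. Chi-square per degree of freedom was 115 and 121 for HoxA2OE replicate 1 against replicates 2 and 3, and 5.46 to 6.61 within wild-type Md. The simulation lacks that wider spread, so its shares do not carry over to the real HoxA2OE calls.

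Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a stricter filter of 1 CPM, a fit of only the groups compared, the same fit with a replicate block, a threshold on the fold (absolute log2 fold change of at least 1), and leaving out each replicate in turn. Fits without mitochondrial genes, without the 3 HoxA2OE libraries and without the E10.5 Mx libraries were added after seeing the data.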

Results

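Gene expression was measured in 47 libraries of cranial neural crest cells from 3 embryonic days. The 3 libraries of E8.5 are progenitors. At E10.5 and E11.5 the cells were split by place into the frontonasal process (FNP), the maxillary (Mx) and mandibular (Md) parts of the first arch, and the second arch (PA2). Each wild-type group had 3 libraries, except Mx at E10.5 with 2. Other groups of 3 were Ezh2cKO (conditional loss of Ezh2) in each subpopulation at E10.5, HoxA2OE (overexpression of Hoxa2) in Md at E10.5, and Hoxa2TempMut (loss of Hoxa2 from a chosen time on) with its Control in PA2 at E11.5. Totals averaged 43.5 ± 0.0792 M counts at E8.5 (M for 1e6, n = 3), 21.3 ± 2.15 M in Md at E10.5 (n = 3) and 47.5 M in HoxA2OE (n = 3). They lay between 18.8 and 49.8 M in single libraries.

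Ezh2 encodes the enzyme of Polycomb repressive complex 2 (PRC2), which marks silent genes by methylating lysine 27 of histone H3. Ezh2 (ENSMUSG00000029687, chromosome 6, 47530274 to 47595341 on GRCm38) lay between 113 and 157 CPM in the 12 Ezh2cKO libraries and between 350 and 405 CPM in the 11 wild-type libraries of E10.5. Averaged over subpopulations it was 137 ± 14.8 CPM (n = 12) against 363 ± 15.8 CPM (n = 11), a log2 fold change of -1.41 ± 0.05 (adjusted p = 4.08e-24). Hoxa2, the homeobox gene that sets the identity of the second arch, lies on chromosome 6 at 52162351 to 52165413 (ENSMUSG00000014704). Hoxa2 reached 92.8 to 124 CPM in the 3 HoxA2OE libraries and 0.248 to 0.297 CPM in those of wild-type Md. In Hoxa2TempMut PA2 it lay between 176 and 195 CPM, below the 268 to 269 CPM of Control, but was not called (log2 fold change -0.54 ± 0.21, adjusted p = 0.503, n = 3 against 3). That error comes from a spread shared over all groups, and the libraries of the 2 groups did not overlap. The missing call is therefore no evidence of an equal level. Wild-type PA2 of E11.5 lay at 183 to 199 CPM, so Hoxa2TempMut was near the wild-type level and Control lay above both. Counts over a whole gene cannot check a deletion of part of it.

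**Figure D1:**
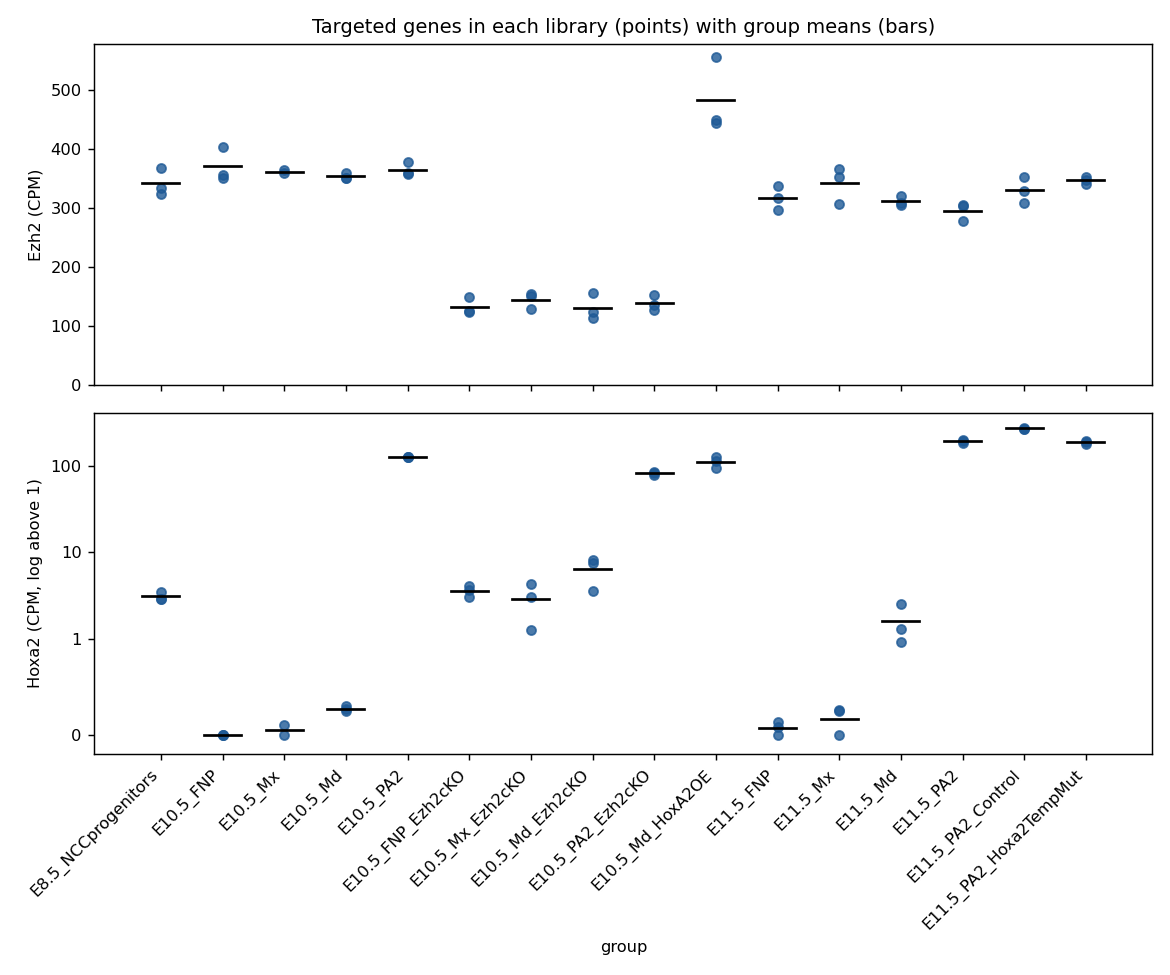
Levels of Ezh2 and Hoxa2 in each library (y axes in CPM, that of Hoxa2 on a log scale above 1; x axis groups; points are libraries and bars group means). All 12 Ezh2cKO libraries lie below 157 CPM of Ezh2, and the 3 HoxA2OE libraries lie at 92.8 to 124 CPM of Hoxa2.

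The genes that mark FNP, the source of the forehead and nose, were sought against the other 3 subpopulations at E10.5. Pax7, a paired-box factor of cranial mesenchyme, reached 194 ± 29.8 CPM in FNP (n = 3) and 0.132 ± 0.171 CPM elsewhere (n = 8), a log2 fold change of 11.87 ± 0.33 (adjusted p = 2.92e-28). Tfap2b reached 345 ± 31.02 against 16.04 ± 21.5 CPM (7.13 ± 0.19, adjusted p = 5.52e-29), and the GDNF receptor Ret 17.8 ± 3.37 against 0.457 ± 0.407 CPM. Alx1, whose loss leads to frontonasal clefts, was at 219 ± 23.5 against 21.5 ± 18.6 CPM (4.32 ± 0.15, adjusted p = 3.30e-25). All 8 frontonasal regulators were higher, 8 adjusted over the list alone (camera adjusted p = 2.09e-75). Of 15 genes of early neural crest specification, 8 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 3.62e-06).

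The arch genes were low in FNP. Hand2, which patterns the distal arch, had 0 counts in FNP against 34.5 ± 26.7 CPM elsewhere, at least 968-fold lower (adjusted p = 1.07e-12). Dlx1 was at 0.125 ± 0.0829 against 130.5 ± 42.8 CPM (log2 fold change -9.87 ± 0.22, adjusted p = 2.01e-31), and Dlx2 at 0.117 ± 0.0139 against 39.1 ± 7.05 CPM. Distal arch regulators were higher in 1 and lower in 9 of 11 genes, the same adjusted over the list alone (camera adjusted p = 9.04e-30). Maxillary and proximal arch regulators were higher in 2 and lower in 6 of 10 genes (camera adjusted p = 1.42e-25). Erythroid genes were lower in 7 of 9, 8 adjusted over the list alone (camera adjusted p = 2.19e-05), led by Hba-x with 10.998 ± 7.53 against 160.1 ± 47.8 CPM. Epithelium genes were higher in 7 of 10, 8 adjusted over the list alone (camera adjusted p = 8.86e-05, adjusted p = 0.0778 with an estimated correlation), with Cdh1 at 1.39 ± 0.849 CPM. In all, 3270 genes were higher and 2400 lower, the most of the 4 subpopulations at this stage. Mitochondrial counts were 30.2% ± 2.92 in FNP, against 22.2% ± 0.549 in Mx, 21.7% ± 2.06 in Md and 22.9% ± 0.725 in PA2. Chi-square per degree of freedom was 29.2 and 34.1 for FNP replicate 1 against replicates 2 and 3, and 5.83 between those. Whether either adds to the calls was not tested.

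**Figure D2:**
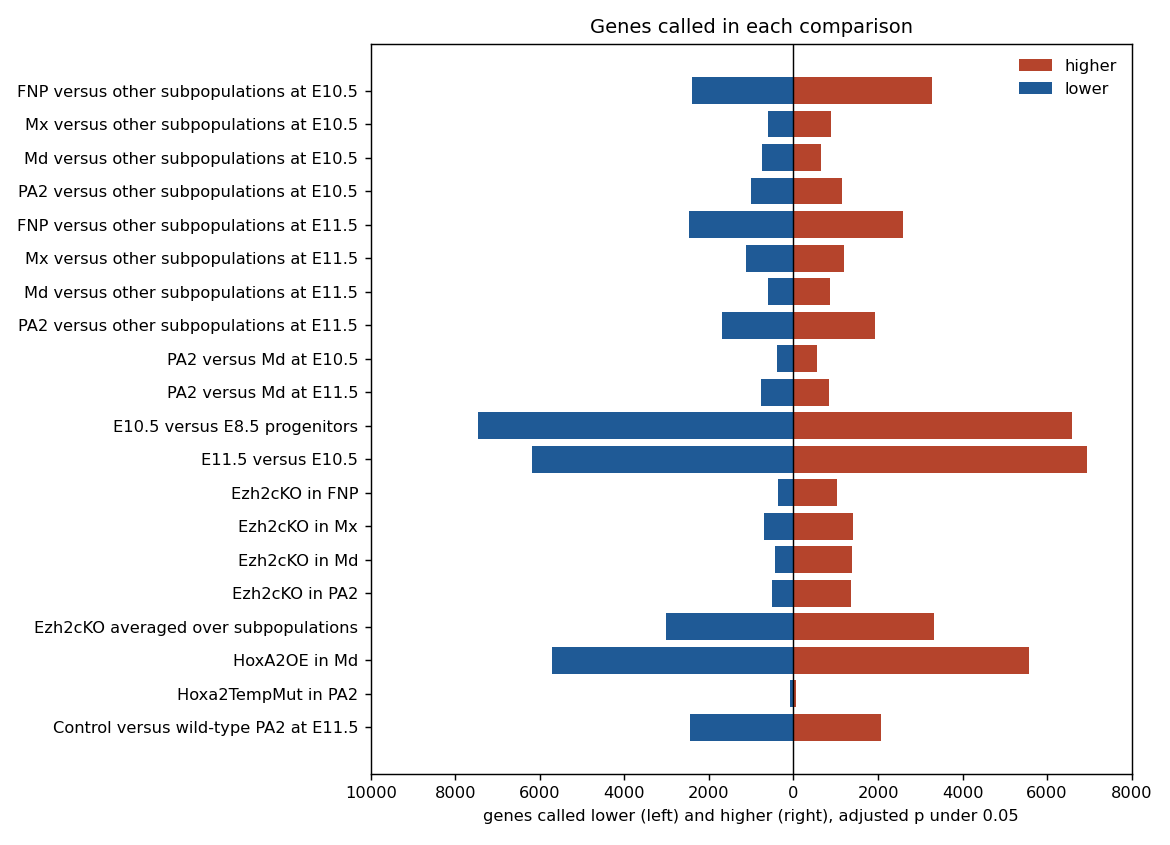
Number of genes called higher (right) and lower (left) in each comparison at an adjusted p under 0.05 among 20560 genes, by edgeR's quasi-likelihood test. The counts run from 128 in Hoxa2TempMut to 14060 between E10.5 and E8.5.

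The maxillary cells of E10.5 were compared in the same way (n = 2 against 9). Lhx6, a LIM factor of oral mesenchyme and teeth, was at 152 ± 0.498 against 26.4 ± 35.8 CPM (log2 fold change 4.48 ± 0.17, adjusted p = 8.49e-23), and Lhx8 at 162 ± 1.01 against 47.05 ± 44.2 CPM (2.34 ± 0.14, adjusted p = 7.56e-17). Maxillary and proximal arch regulators were higher in 7 of 10 genes, with 7 higher and 1 lower adjusted over the list alone (camera adjusted p = 5.18e-44). Genes of differentiated neurons and glia were higher in 11 of 12, 12 adjusted over the list alone (camera adjusted p = 3.84e-82). Neurod1 was at 30.8 ± 4.88 against 0.241 ± 0.294 CPM (7.53 ± 0.43, adjusted p = 3.16e-17), and Stmn2 at 21.8 ± 0.552 against 0.351 ± 0.395 CPM (6.72 ± 0.26, adjusted p = 1.49e-22). The sensory neuron factor Pou4f1 reached 23.5 ± 4.63 against 0.159 ± 0.123 CPM (7.22 ± 0.37, adjusted p = 7.49e-19), and 6 of 17 neural regulators were higher, 6 adjusted over the list alone (camera adjusted p = 6.83e-12). Hedgehog targets were lower in 5 of 8, 6 adjusted over the list alone (camera adjusted p = 7.97e-10), led by Foxf1 at 3.09 ± 0.673 against 16.8 ± 7.22 CPM. Without Mx replicate 1 or 2, the 1496 calls of this comparison became 870 or 911.

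Md forms the lower jaw. Hand2 was at 64.2 ± 3.91 CPM in Md (n = 3) and 13.1 ± 20.3 CPM elsewhere (n = 8; log2 fold change 7.56 ± 0.29, adjusted p = 2.43e-22), and Hand1 at 73.6 ± 11.6 against 3.23 ± 4.83 CPM (6.89 ± 0.27, adjusted p = 1.02e-22). Pitx1, a homeobox gene of the oral side of the first arch, was at 67.8 ± 3.14 against 0.509 ± 0.419 CPM (7.43 ± 0.30, adjusted p = 2.99e-22). Distal arch regulators were higher in 9 and lower in 1 of 11 genes, the same adjusted over the list alone (camera adjusted p = 2.61e-116). Hedgehog targets were higher in 7 of 8, 8 adjusted over the list alone (camera adjusted p = 3.93e-12), with Foxf1 at 25.6 ± 3.46 against 9.29 ± 4.99 CPM. Genes of early neural crest specification were lower in 8 of 15, 8 adjusted over the list alone (camera adjusted p = 1.52e-13), among them Erbb3 at 1.27 ± 0.495 against 15.4 ± 9.52 CPM and Sox10 at 0.937 ± 0.450 against 10.6 ± 11.2 CPM. Pou3f3, a marker of the proximal arch, was at 4.00 ± 0.367 against 29.5 ± 8.46 CPM (-2.83 ± 0.18, adjusted p = 2.54e-16).

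PA2 forms the hyoid and stapes and is the Hox-positive subpopulation. Hoxa2 was at 125 ± 1.25 CPM (n = 3) against 0.108 ± 0.134 CPM (n = 8; log2 fold change 11.58 ± 0.31, adjusted p = 1.03e-27). Hoxa3 was at 12.5 ± 1.86 CPM with 1 count elsewhere, a ratio of 2768 with a counting interval of 495 to 109440 (adjusted p = 9.62e-20). Anterior Hox genes were higher in 5 of 12, 5 adjusted over the list alone (camera adjusted p = 3.99e-31), and candidate Hoxa2-activated genes were higher in 6 and lower in 1 of 7 (camera adjusted p = 9.69e-63). Dlx3 reached 119 ± 15.3 against 15.4 ± 22.5 CPM (5.07 ± 0.15, adjusted p = 1.03e-27), and 10 of 11 distal arch regulators were higher with 1 lower, as adjusted over the list alone (camera adjusted p = 1.92e-93). Frontonasal regulators were lower in 6 of 8, 7 adjusted over the list alone (camera adjusted p = 2.01e-60). Among them, Pax3 was at 0.440 ± 0.2503 against 74.2 ± 69.3 CPM (-6.75 ± 0.27, adjusted p = 3.75e-23) and Alx1 at 1.73 ± 0.229 against 94.0 ± 100.3 CPM (-5.002 ± 0.23, adjusted p = 6.72e-21).

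A day later the same 4 subpopulations were compared with 3 libraries against 9. In FNP, Pax7 was at 159.8 ± 13.1 against 1.01 ± 1.28 CPM (log2 fold change 7.83 ± 0.22, adjusted p = 1.75e-28) and the zinc-finger factor Gata2 at 137 ± 17.9 against 1.98 ± 2.24 CPM (6.90 ± 0.14, adjusted p = 3.85e-33). Cartilage and bone genes were higher in 9 and lower in 2 of 15, with 10 higher and 2 lower adjusted over the list alone (camera adjusted p = 5.63e-15). Sox9, the master regulator of cartilage, was at 198 ± 14.1 against 66.8 ± 28.8 CPM (1.73 ± 0.08, adjusted p = 1.67e-20), and the growth factor Bmp4 at 112 ± 16.3 against 32.4 ± 12.7 CPM (1.89 ± 0.11, adjusted p = 1.38e-17). In Mx, Lhx6 was at 174 ± 11.1 against 28.3 ± 33.4 CPM (3.86 ± 0.15, adjusted p = 1.13e-22) and Foxl2 at 16.4 ± 0.991 against 0.616 ± 0.663 CPM (5.58 ± 0.24, adjusted p = 2.95e-20). Neuron and glia genes were higher in Mx in 7 of 12, 9 adjusted over the list alone (camera adjusted p = 6.83e-06). Neurod1 among them was at 0.929 ± 1.00 CPM, and Stmn2 at 38.4 ± 6.07 against 16.8 ± 19.4 CPM.

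In Md at E11.5, Hand1 was at 12.5 ± 3.004 against 0.0760 ± 0.0775 CPM (log2 fold change 7.62 ± 0.34, adjusted p = 3.19e-21) and Pitx1 at 47.8 ± 3.01 against 1.04 ± 1.28 CPM (6.95 ± 0.28, adjusted p = 2.85e-22). All 8 hedgehog targets were higher, 8 adjusted over the list alone (camera adjusted p = 1.88e-26), led by Foxd1 at 22.2 ± 1.91 against 5.50 ± 3.62 CPM (2.28 ± 0.14, adjusted p = 4.49e-16). Maxillary and proximal arch regulators were higher in 8 and lower in 2 of 10, the same adjusted over the list alone (camera adjusted p = 3.17e-41). In PA2, Hoxa2 was at 192 ± 8.11 against 0.605 ± 0.839 CPM (9.49 ± 0.22, adjusted p = 1.58e-29), and anterior Hox genes were higher in 11 of 12, 12 adjusted over the list alone (camera adjusted p = 4.62e-53). Posterior Hox genes were higher in 5 of 27, 5 adjusted over the list alone (camera adjusted p = 0.00419, adjusted p = 0.424 with an estimated correlation). The Notch effector Hey2 was at 0.500 ± 0.151 against 45.7 ± 25.8 CPM in PA2 (-6.32 ± 0.27, adjusted p = 1.86e-22), and Alx1 at 1.19 ± 0.314 against 145 ± 154 CPM (-6.07 ± 0.23, adjusted p = 1.05e-23).

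PA2 was also set against Md alone, the Hox-positive against the Hox-negative arch. Candidate Hoxa2-repressed genes were lower in PA2 in 5 of 7 at E10.5, 6 adjusted over the list alone (camera adjusted p = 9.06e-55), and in 7 of 7 at E11.5 (camera adjusted p = 8.59e-43). Pitx1 was at 0.920 ± 0.209 against 67.8 ± 3.14 CPM at E10.5 (log2 fold change -6.20 ± 0.40, adjusted p = 2.06e-15, n = 3 against 3). Pax3 was at 0.440 ± 0.2503 against 11.9 ± 1.56 CPM at E10.5 and 0.520 ± 0.148 against 49.2 ± 4.24 CPM at E11.5. At E11.5, Hoxa3 was at 30.7 ± 3.32 against 0.0960 ± 0.0905 CPM (8.28 ± 0.43, adjusted p = 3.64e-17). Gad2, an enzyme of GABA synthesis, had 7.66 ± 1.31 CPM in PA2 and 3 counts in Md, a ratio of 269 with a counting interval of 91.7 to 1308 (adjusted p = 3.66e-09). Cartilage and bone genes were lower in PA2 at E11.5 in 8 of 15 and higher in 1, with 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.60e-21). Hedgehog targets were lower in 7 of 8, 7 adjusted over the list alone (camera adjusted p = 4.02e-27). The calls numbered 560 higher and 400 lower at E10.5, and 842 and 777 at E11.5. The 960 calls at E10.5 became 1746 in a fit of only the groups compared.

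The E8.5 progenitors were compared with the mean of the E10.5 wild-type subpopulations. Sox1, a marker of neural progenitors, was at 0.0383 ± 0.0722 CPM at E10.5 (n = 11) and 134 ± 31.7 CPM at E8.5 (n = 3; log2 fold change -11.95 ± 0.29, adjusted p = 6.06e-27). Pax5 and En2 of the midbrain and Shh of the floor plate had 0 counts at E10.5. Pax5 was at 31.0 ± 7.53 CPM at E8.5, at least 3010.5-fold above E10.5, En2 at 19.6 ± 0.167 CPM, at least 1877-fold, and Shh at 13.8 ± 2.79 CPM, at least 1321-fold (adjusted p = 1.44e-23, 9.43e-19 and 6.87e-20). Neural regulators were lower in 17 of 17, 17 adjusted over the list alone (camera adjusted p = 1.81e-24). Regulators of other lineages were lower in 15 and higher in 1 of 18, with 16 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.59e-06). The transcription factor Bcl11a rose from 0.312 ± 0.0924 to 268 ± 56.0 CPM (9.71 ± 0.13, adjusted p = 3.83e-40) and the stomach and jaw gene Barx1 from 0.0375 ± 0.0146 to 39.2 ± 28.1 CPM (9.04 ± 0.35, adjusted p = 1.14e-24). Endothelium and epithelium genes were lower in 10 of 10 each, 10 adjusted over the list alone (camera adjusted p = 8.81e-13 and 1.65e-10). Proliferation genes were lower in 12 and higher in 1 of 15 (camera adjusted p = 0.0398, adjusted p = 0.282 with an estimated correlation). The globin gene Hba-x lay at 517.5 to 711 CPM at E8.5 and at 4.68 to 222 CPM in wild type at E10.5. A difference in cell content between the stages, or a library batch, cannot be told apart from a change within the crest.

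From E10.5 to E11.5 the heterochronic gene Lin28a, which blocks the maturation of let-7, fell from 17.8 ± 6.01 CPM (n = 11) to 0.395 ± 0.257 CPM (n = 12; log2 fold change -5.77 ± 0.21, adjusted p = 1.23e-24). The receptor gene Igdcc3 fell from 219 ± 42.6 to 14.6 ± 4.48 CPM (-3.96 ± 0.11, adjusted p = 1.04e-28). Pax1 rose from 0.389 ± 0.452 to 42.8 ± 40.3 CPM (6.52 ± 0.27, adjusted p = 2.20e-22) and the collagen gene Col8a1 from 0.207 ± 0.139 to 18.4 ± 16.5 CPM (5.94 ± 0.22, adjusted p = 1.56e-24). Cartilage and bone genes rose in 10 and fell in 5 of 15, the same adjusted over the list alone (camera adjusted p = 0.168). Proliferation genes fell in 10 of 15, 10 adjusted over the list alone (camera adjusted p = 0.117). In all, 6938 genes rose and 6184 fell. On principal component 2 of log2 levels, wild-type libraries ran from -43.1 to -22.6 at E10.5 and from 26.7 to 40.6 at E11.5. The 3 HoxA2OE libraries of E10.5 lay at 24.99 to 60.7 and the E8.5 libraries at 61.6 to 79.7, both on the side of E11.5. This axis therefore does not follow the order of the stages. All 22 column names that appear 2 times belong to wild-type or Ezh2cKO libraries of E10.5. What the repeat marks is not stated. A library batch that follows stage was not tested and cannot be told apart from stage.

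Ezh2cKO asked which genes Polycomb keeps silent in each subpopulation. Averaged over the 4, posterior Hox genes rose in 27 of 27, 27 adjusted over the list alone (camera adjusted p = 3.90e-75), and anterior Hox genes in 11 of 12, 11 adjusted over the list alone (camera adjusted p = 3.57e-37). Hoxa10 was at 13.3 ± 7.64 CPM (n = 12) with 3 counts in the 11 wild-type libraries, a ratio of 1253 with a counting interval of 428 to 6077 (adjusted p = 1.46e-15). Hoxd13, a gene of the tail and digits, was at 10.1 ± 4.64 against 0.0162 ± 0.0233 CPM (log2 fold change 9.58 ± 0.36, adjusted p = 3.07e-20). Posterior Hox genes rose in 26 of 27 in FNP, 27 in Mx, 27 in Md and 23 in PA2, and anterior ones in 12, 10, 10 and 7 of 12.

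Regulators of other lineages rose in 13 of 18, 14 adjusted over the list alone (camera adjusted p = 7.58e-27). The limb and heart gene Tbx5 was at 4.64 ± 1.87 against 0.0147 ± 0.0205 CPM (log2 fold change 8.23 ± 0.33, adjusted p = 1.23e-21), and Gata4 of heart and gut at 2.83 ± 0.670 against 0.0139 ± 0.0337 CPM (7.88 ± 0.41, adjusted p = 1.19e-15). Neural regulators rose in 12 of 17, 12 adjusted over the list alone (camera adjusted p = 2.09e-13). En2, found in the E8.5 libraries, was at 1.95 ± 1.08 CPM with 0 counts in wild type, at least 180.2-fold higher (adjusted p = 4.34e-13), and Otx2 was at 2.50 ± 0.647 against 0.356 ± 0.579 CPM (4.70 ± 0.34, adjusted p = 5.89e-14). The cerebellar and somite factor Zic1 rose from 0.611 ± 1.14 to 10.2 ± 5.59 CPM (7.54 ± 0.33, adjusted p = 3.33e-20).

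Cell-cycle inhibitors rose in 6 of 7, 6 adjusted over the list alone (camera adjusted p = 6.61e-12). Cdkn2a, the senescence gene kept off by Polycomb, was at 0.363 ± 0.189 CPM with 0 counts in wild type, at least 34.9-fold higher (adjusted p = 8.10e-08). Cdkn2c rose from 0.824 ± 0.201 to 8.20 ± 0.915 CPM (log2 fold change 3.32 ± 0.14, adjusted p = 1.34e-21) and Cdkn2b from 0.135 ± 0.197 to 2.63 ± 1.41 CPM (5.61 ± 0.32, adjusted p = 1.19e-16). Proliferation genes fell in 4 of 15, 8 adjusted over the list alone (camera adjusted p = 0.0101, adjusted p = 0.116 with an estimated correlation), with Mcm6 at 144 ± 14.1 against 193 ± 12.2 CPM (-0.43 ± 0.05, adjusted p = 5.17e-10). Of 13 p53 targets, 6 rose and 1 fell, 7 and 2 adjusted over the list alone (camera adjusted p = 0.186), with Pmaip1 at 11.4 ± 12.7 against 5.27 ± 6.59 CPM.

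Polycomb genes themselves moved. Bmi1, a core part of PRC1, rose from 56.0 ± 5.04 to 153 ± 14.988 CPM (log2 fold change 1.45 ± 0.06, adjusted p = 1.76e-22). Components of canonical PRC1 rose in 5 of 12, 5 adjusted over the list alone (camera adjusted p = 2.20e-05). Those of PRC2 rose in 2 and fell in 7 of 12, Ezh2 among the 7, the same adjusted over the list alone (camera adjusted p = 0.00242). The fall of the targeted Ezh2 adds to this p-value, and the list was not tested without it. Besides Ezh2, Eed fell from 54.1 ± 5.05 to 44.5 ± 3.03 CPM (-0.28 ± 0.07, adjusted p = 0.00273), while Phf19 rose from 1.15 ± 0.498 to 2.99 ± 0.497 CPM (1.45 ± 0.17, adjusted p = 8.24e-09).

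Genes of other cell types moved less evenly in Ezh2cKO. Immediate early genes rose in 10 of 12, 10 adjusted over the list alone (camera adjusted p = 1.74e-04), with Fos at 19.4 ± 4.14 against 8.29 ± 3.95 CPM (log2 fold change 1.42 ± 0.15, adjusted p = 3.03e-10). Epithelium genes rose in 6 and fell in 1 of 10 (camera adjusted p = 1.91e-04, adjusted p = 0.0527 with an estimated correlation), with Krt18 at 2.88 ± 0.819 against 1.05 ± 0.508 CPM. Muscle genes rose in 3 of 10 (camera adjusted p = 0.0863), endothelium genes in 2 of 10 (camera adjusted p = 0.425), and cartilage and bone genes rose in 6 and fell in 4 of 15 (camera adjusted p = 0.563). Erythroid genes fell in 4 of 9 (camera adjusted p = 0.148) and leukocyte genes in 1 of 5 (camera adjusted p = 0.671). The mitochondrial share of counts was also higher in Ezh2cKO, at 27.0% ± 1.79 against 22.2% ± 0.549 in Mx, 27.9% ± 2.80 against 21.7% ± 2.06 in Md and 28.8% ± 1.81 against 22.9% ± 0.725 in PA2, but 30.5% ± 1.66 against 30.2% ± 2.92 in FNP.

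The wild-type level of the genes that moved was then read. Of the 3320 genes that rose, 42.3% lay below 1 CPM in wild type, with a median of 1.62 CPM, and of the 3019 that fell, 2.85%, with a median of 55.2 CPM. Of all genes tested, 27.9% lay below 1 CPM, with a median of 6.74 CPM. A fall is harder to call from a low level, so the contrast cannot be read as a property of the genes alone. At a log2 fold change of at least 1, 1313 rose and 66 fell, of which 76.7% and 66.7% lay below 1 CPM. In all 4 subpopulations, 501 of the 2392 genes that rose in any did so. Of the 1358 that fell in any, 43 fell in all 4. These 4 comparisons share no library, but whether they share embryos is not stated.

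Genes that mark one subpopulation at E11.5 were then followed into the Ezh2cKO cells of the others. Over the 12 pairs of a positional set and a subpopulation other than its own, set members rose 1113 times and fell 82 times. Between 19.6% (Mx genes in FNP) and 32.9% (PA2 genes in Mx) of a set rose, against 5.94% to 9.24% of genes of matched wild-type level. Genes of the subpopulation's own set rose as well, in 16.4% (FNP), 21.0% (Mx), 16.9% (Md) and 25.05% (PA2). All 16 pairs passed camera, and all but Mx genes in Mx also with an estimated correlation (adjusted p = 0.0585). At E8.5, 39.7% of FNP genes, 50.7% of Mx, 52.0% of Md and 57.0% of PA2 genes lay below 1 CPM, against 28.2% of all genes tested.

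**Figure D3:**
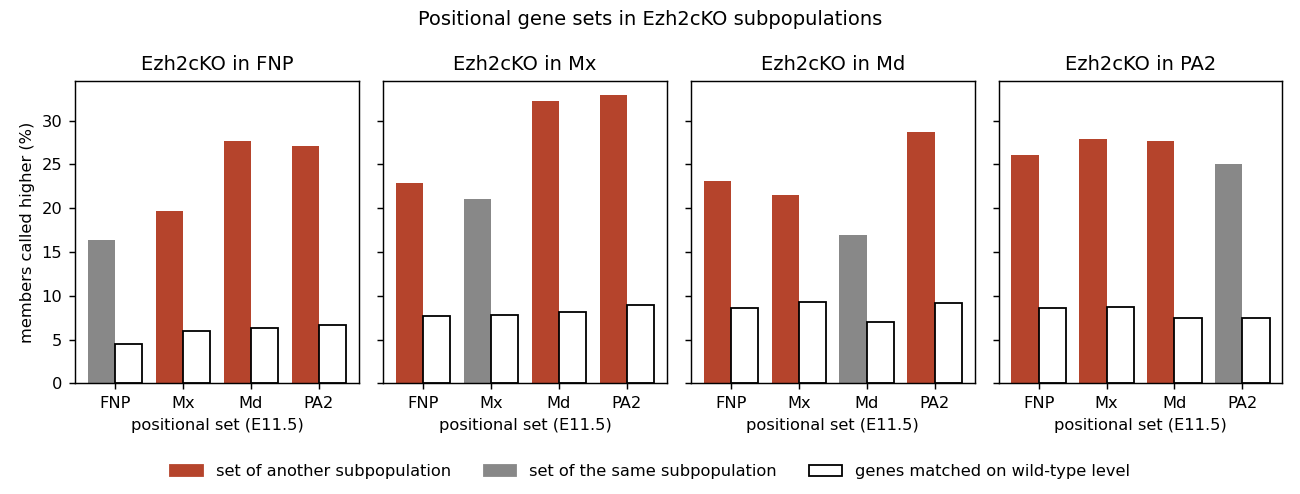
Share of each positional set of E11.5 that rose in Ezh2cKO of each subpopulation at E10.5 (percent), beside the mean share of sets matched on wild-type level. Foreign sets rose in 19.6% to 32.9% of genes and matched sets in 4.52% to 9.24%.

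The lists showed which regulators appeared where. In FNP, distal arch regulators rose in 8 of 11, 9 adjusted over the list alone (camera adjusted p = 2.94e-16), with Hand1 at 2.60 ± 0.381 against 0.0908 ± 0.0465 CPM (log2 fold change 4.74 ± 0.60, adjusted p = 2.18e-07, n = 3 against 3) and Hand2 at 0.612 ± 0.263 CPM with 0 counts in wild type, at least 17.4-fold. Candidate Hoxa2-activated genes rose there in 6 of 7, 6 adjusted over the list alone (camera adjusted p = 2.57e-34), with Hoxa2 at 3.58 ± 0.497 CPM and 0 counts in wild type, at least 101.9-fold (adjusted p = 2.07e-10). That list holds Hoxa2 and Hoxb2, both from 0 counts in FNP, and was not tested without them. In PA2, frontonasal regulators rose in 5 of 8, 6 adjusted over the list alone (camera adjusted p = 2.48e-14), and candidate Hoxa2-repressed genes in 6 of 7, 7 adjusted over the list alone (camera adjusted p = 6.64e-16). Alx1 rose from 1.73 ± 0.229 to 9.63 ± 0.611 CPM (2.48 ± 0.25, adjusted p = 1.37e-09) and Pitx1 from 0.920 ± 0.209 to 4.80 ± 1.42 CPM (2.38 ± 0.43, adjusted p = 1.12e-04). The effect differed between subpopulations for 335 genes (546 in a fit of only the groups compared). Without Mx wild-type replicate 1 or 2, the 2111 calls in Mx became 997 or 722.

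HoxA2OE asked what Hoxa2 does in Md, where it is normally off. Hoxa2 rose to 109.9 ± 15.9 CPM from 0.270 ± 0.0251 CPM (log2 fold change 8.65 ± 0.37, adjusted p = 1.13e-19, n = 3 against 3), near the 125 ± 1.25 CPM of wild-type PA2. All 7 candidate Hoxa2-repressed genes fell, 7 adjusted over the list alone (camera adjusted p = 1.28e-06), led by Pitx1 from 67.8 ± 3.14 to 5.40 ± 3.57 CPM (-3.61 ± 0.32, adjusted p = 9.07e-12) and Six2 from 17.4 ± 3.53 to 1.40 ± 0.733 CPM (-3.57 ± 0.27, adjusted p = 1.79e-13). Pax3 fell from 11.9 ± 1.56 to 0.386 ± 0.248 CPM (-4.90 ± 0.28, adjusted p = 7.47e-17). Candidate Hoxa2-activated genes rose in 6 of 7, Hoxa2 included, 6 adjusted over the list alone (camera adjusted p = 2.45e-05), with Zfp503 at 63.3 ± 15.04 against 23.2 ± 2.14 CPM (1.45 ± 0.13, adjusted p = 1.18e-11). The overexpressed Hoxa2 adds to the list p-value, and the list was not tested without it. The homeobox gene Irx2 rose from 0.979 ± 0.297 to 11.6 ± 0.779 CPM (3.53 ± 0.20, adjusted p = 5.51e-17). Hand2 stayed on, at 99.5 ± 48.5 against 64.2 ± 3.91 CPM (0.63 ± 0.21, adjusted p = 0.0126). Errors and p-values of this comparison rest on a spread shared over all 16 groups. Chi-square per degree of freedom ran from 11.3 to 121 between HoxA2OE libraries and from 5.46 to 6.61 within wild-type Md. The errors and p-values for HoxA2OE may therefore be too small.

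Genes higher in PA2 than in Md at E11.5 rose in HoxA2OE in 117 and fell in 48 of 436, 111 and 39 adjusted over the list alone (camera adjusted p = 0.0125, adjusted p = 0.221 with an estimated correlation). Genes higher in Md fell in 102 and rose in 55 of 337, 97 and 52 adjusted over the list alone (camera adjusted p = 0.0166, adjusted p = 0.221 with an estimated correlation). Over all genes tested, 5569 of 20560 rose and 5708 fell. Moves toward PA2 in both sets therefore lay near the share over all genes, while moves the other way lay below it. Proliferation genes rose in 8 and fell in 2 of 15 (camera adjusted p = 0.00480, adjusted p = 0.172 with an estimated correlation), with Pcna at 414 ± 153 against 154 ± 8.94 CPM. Erythroid genes fell in 7 of 9, 8 adjusted over the list alone (camera adjusted p = 1.01e-04, adjusted p = 0.0870 with an estimated correlation), with Hba-x at 4.68 ± 2.39 against 125 ± 19.5 CPM. AC132131.1 rose from 0.137 ± 0.0195 to 20.1 ± 6.34 CPM (7.18 ± 0.41) and Anks1b from 0.0908 ± 0.0428 to 5.12 ± 2.38 CPM (5.75 ± 0.54, adjusted p = 7.67e-17 and 3.45e-11). They lie side by side on chromosome 10, at 89873672 to 90683697 and 90829843 to 90971457. In all, 5569 of 20560 genes rose and 5708 fell. At a log2 fold change of at least 1, 1455 rose and 2848 fell, and a fit of only the 2 groups called 6400 in place of 11277. HoxA2OE replicate 1 stands apart, with 45.9% mitochondrial counts against 28.5% in each of the other 2, a TMM factor of 0.514 and 19632 genes detected, and a batch cannot be told apart from the genotype.

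Hoxa2TempMut asked what PA2 still needs Hoxa2 for after its early role. Candidate Hoxa2-repressed genes rose in 5 of 7, 6 adjusted over the list alone (camera adjusted p = 5.91e-22), among them Pitx1 from 3.75 ± 0.484 to 10.8 ± 2.06 CPM (log2 fold change 1.52 ± 0.32, adjusted p = 0.00703, n = 3 against 3) and Alx4 from 14.8 ± 2.76 to 34.2 ± 1.96 CPM (1.20 ± 0.13, adjusted p = 1.35e-07). Candidate Hoxa2-activated genes fell in 1 of 7, 5 adjusted over the list alone (camera adjusted p = 1.21e-09). The 1 was Meis2, a Hox cofactor, from 1039 ± 62.0 to 684 ± 16.2 CPM (-0.60 ± 0.10, adjusted p = 1.96e-04). The list of activated genes holds the targeted Hoxa2 and was not tested without it. The neural adhesion gene Cntn3 rose from 3.56 ± 0.146 to 15.9 ± 1.19 CPM (2.15 ± 0.19, adjusted p = 8.40e-10). The BMP antagonist Grem1 fell from 19.4 ± 5.45 to 5.56 ± 0.970 CPM (-1.80 ± 0.25, adjusted p = 8.97e-06) and Onecut2 from 65.6 ± 14.6 to 22.7 ± 1.95 CPM (-1.53 ± 0.17, adjusted p = 1.28e-07). Of 15 cartilage and bone genes, 3 rose, 5 adjusted over the list alone (camera adjusted p = 2.13e-08).

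Other lists moved with few single calls in Hoxa2TempMut. Of 13 p53 targets, 1 rose, 3 adjusted over the list alone (camera adjusted p = 1.50e-09). The 1 was Eda2r, from 1.13 ± 0.412 to 4.75 ± 0.110 CPM (log2 fold change 2.07 ± 0.22, adjusted p = 1.14e-07). Frontonasal regulators rose in 3 of 8 (camera adjusted p = 2.68e-04, adjusted p = 0.0560 with an estimated correlation). Genes higher in PA2 than in Md at E10.5 fell in 31 and rose in 1 of 260, 69 and 11 adjusted over the list alone (camera adjusted p = 2.10e-27). Genes higher in Md rose in 16 and fell in 1 of 187, 33 and 8 adjusted over the list alone (camera adjusted p = 1.79e-06). In all, 53 genes rose and 75 fell. The mix of sexes differed, with Xist at 4.73 CPM in Control replicate 3 and the Y-linked Ddx3y at 0.139 CPM in Hoxa2TempMut replicate 1. Whether it adds to the calls was not tested. The 128 calls became 247 in a fit of only the groups compared and 75 without Control replicate 2, and the 31 became 20 without Control replicate 2 or 3.

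Gain and loss of Hoxa2 were compared gene by gene, and these comparisons share no library. Of the genes called, 41 rose in HoxA2OE and fell in Hoxa2TempMut, where independent lists would share 20.3 (odds ratio 3.26, 95% interval 2.02 to 5.31, Fisher's exact test, adjusted p = 2.39e-06). Another 24 fell in HoxA2OE and rose in Hoxa2TempMut, where independent lists would share 14.7 (odds ratio 2.16, 1.20 to 3.84, adjusted p = 0.0109). Fewer moved the same way, with 12 higher in both (14.4 if independent, adjusted p = 0.538) and 7 lower in both (20.8 if independent, adjusted p = 2.81e-04). Among the 65 opposite genes, Pitx1, Six2, Alx4, Lhx6 and Nkx3-2 are candidate Hoxa2-repressed genes and Meis2 a candidate activated one.

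**Figure D4:**
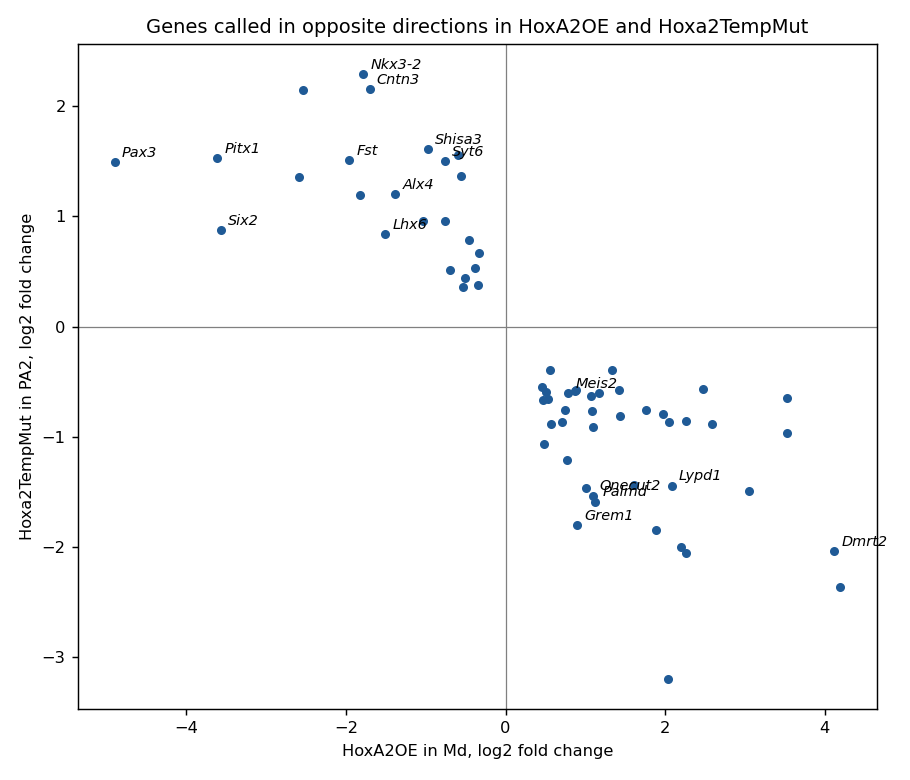
Log2 fold changes in HoxA2OE (x axis) and Hoxa2TempMut (y axis) of the 65 genes called in both in opposite directions, each point a gene. Of these, 41 lie at the lower right and 24 at the upper left.

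Control PA2 and wild-type PA2 at E11.5 are named apart in the labels, which do not say how they differ. The comparison serves as a background for Hoxa2TempMut. Control had 2078 genes higher and 2459 lower. Hoxa2 lay at 268 to 269 CPM in Control and at 183 to 199 CPM in wild type. Muscle genes were higher in 8 of 10, 8 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.57e-05), with cardiac actin Actc1 at 31.4 ± 9.64 against 5.50 ± 3.11 CPM (log2 fold change 2.52 ± 0.31, adjusted p = 1.00e-07, n = 3 against 3) and Myf5 at 0.947 ± 0.145 against 0.115 ± 0.0506 CPM (3.01 ± 0.52, adjusted p = 4.10e-05). Immediate early genes were higher in 7 of 12, 7 adjusted over the list alone (camera adjusted p = 3.26e-06), with Fosb at 27.2 ± 8.48 against 5.71 ± 2.49 CPM (2.25 ± 0.32, adjusted p = 1.47e-06). Candidate Hoxa2-repressed genes were higher in 4 of 7, 5 adjusted over the list alone (camera adjusted p = 5.97e-05, adjusted p = 0.0661 with an estimated correlation), with Alx4 at 14.8 ± 2.76 against 5.49 ± 0.443 CPM. Hedgehog targets were higher in 6 of 8 (camera adjusted p = 0.00374, adjusted p = 0.0884 with an estimated correlation), with Ptch1 at 109.9 ± 9.61 against 69.1 ± 2.42 CPM. Endothelium genes were lower in 4 of 10 (camera adjusted p = 0.00374, adjusted p = 0.0951 with an estimated correlation), with Kdr at 1.83 ± 0.375 against 4.75 ± 1.05 CPM. Genes higher in PA2 than in Md at E10.5 were split, with 22 higher and 21 lower of 260 (camera adjusted p = 0.828). Genes higher in Md were higher in Control in 39 and lower in 9 of 187, 40 and 10 adjusted over the list alone (camera adjusted p = 2.42e-04, adjusted p = 0.113 with an estimated correlation).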

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

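The tests of mitochondrial share, of a batch in HoxA2OE and of a maxillary program, and the fits without mitochondrial genes, without the 3 HoxA2OE libraries and without the E10.5 Mx libraries, were chosen after the result was seen.

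The effect of Ezh2cKO differed between subpopulations for 335 genes in a test of the difference itself. Hoxa2 differed most clearly among the genes followed by name (adjusted p = 5.02e-12), at least 101.9-fold higher in FNP, where wild type had 0 counts, with log2 fold changes of 5.52, 4.57 and -0.61 in Mx, Md and PA2. Hoxb2 (adjusted p = 3.34e-11) also rose in the 3 Hox-negative subpopulations and was not called in PA2. Hoxa3 (adjusted p = 8.94e-07) rose in all 4, at least 29.5-fold in Mx and 71.4-fold in Md, where wild type had 0 counts, and by a log2 fold change of 1.03 in PA2, where wild type already expresses it. Alx1 (adjusted p = 1.53e-06) went the other way, with a log2 fold change of 2.48 in PA2 and -0.09 in FNP, its main site in wild type. Hand2 (adjusted p = 4.17e-04) rose at least 17.4-fold in FNP, from 0 counts, and was not called in Md, where it is on in wild type. Gbx2 (adjusted p = 3.16e-09), of the distal arch list and at 8.05 CPM over the other wild-type subpopulations, rose in FNP from 1 count. Its ratio there was 108.4 with a counting interval of 19.03 to 4320.2. Zic1 (adjusted p = 8.72e-06) rose at least 151.7-fold in Mx, from 0 counts, and by a log2 fold change of 2.96 in FNP. The small nuclear RNA gene U1 (adjusted p = 4.46e-04) and Nr1h5 (adjusted p = 0.0116) rose in FNP, U1 from 1 count (ratio 495.8, counting interval 88.6 to 19624) and Nr1h5 by a log2 fold change of 8.95, and had changes below 0 elsewhere. U1 lies inside Nr1h5 on chromosome 3. Nr1h5 also had 0 counts in HoxA2OE against 41.2 ± 9.09 CPM in wild-type Md, 1 count in wild type at E11.5, and 19.1 ± 24.3 CPM in Ezh2cKO Mx, so its level is not tied to Ezh2 alone, and the cause was not tested. Groups here have at most 3 libraries, too few for a test of single outlying libraries.

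HoxA2OE had 11277 genes called, against 128 in Hoxa2TempMut. The 11277 rest on a spread shared over all groups, which may understate that of the HoxA2OE libraries. A loss of counts that depends on gene length is argued against, since 6332 genes were called after correcting for it and 6400 before, in the fit of only these 2 groups. Mitochondrial RNA taking a larger share stays open, since TMM already scales for it and leaving those genes out moved little (11292 genes called), a reading settled after the result was seen. A batch shared by the 3 HoxA2OE libraries cannot be told apart from the genotype. The share of called genes in the PA2 or Md sets of E11.5 in the matching direction, 1.942%, decides nothing, since sets of 436 and 337 genes keep it low whatever the cause.

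Neuronal genes were higher in Mx at E10.5. Of 10 sensory ganglion genes, 6 were called higher there, among them Tlx3, Ntrk3 and Scn9a, so sensory ganglion cells carried into the E10.5 Mx samples stay open. A maxillary neural crest program held at both stages stays open too, since 7 members of the neuron and glia list were higher in Mx at E11.5. The sensory ganglion genes were not held, with Ntrk2 and Ntrk3 lower in Mx at E11.5 (log2 fold changes -2.74 and -1.26) and only Runx3 higher. Mx had 2 libraries at E10.5, and the crest itself gives rise to ganglion neurons, so the tables do not decide between them.

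Control PA2 differed from wild-type PA2 in 4537 genes. Of the stage genes called in Control, 73.032% differed in the direction of E10.5, which an earlier stage of the Control embryos could give. Of 8 skeletal muscle genes, 2 were higher (Chrna1 and Myl1), which the rule written before the test reads as evidence against muscle precursor cells carried into the Control samples, as does the sort by fluorescence, meant to remove such cells. They are left open, a reading chosen after the result was seen, because the count lies at the bound of that rule and 8 of 10 genes of the planned muscle list, Myf5 among them, were higher. The labels do not say how Control and wild type differ, and no explanation besides these was tested.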

How the results depend on the processing

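The fits without mitochondrial genes, without the 3 HoxA2OE libraries and without the E10.5 Mx libraries were chosen after the result was seen. Of 1418 pairs of a named gene and a comparison, the fold threshold kept 1127 and ended 291, DESeq2 kept 1383 and ended 35, its size factors in edgeR kept 1404 and ended 14, no filter kept 1393 and ended 24, and the stricter filter kept 1370 and ended 9. Fitting only the groups compared kept 1311 and ended 30, without mitochondrial genes 1408 were kept and 8 ended, without HoxA2OE 1328 and 2, and without E10.5 Mx 464 and 41. Leaving out each library kept 14704 of 15556 values, ended 851 and took 1, that of En2, to 0. Foxf1 in FNP at E10.5 reversed to -0.1023 without the E10.5 Mx libraries. Foxf1 was lower in Mx than elsewhere, so leaving Mx out raised the mean that FNP was compared with. En2 in Md at E11.5 ran from 0 without Md replicate 2 to 4.4968 without Md replicate 3. It rests on 6 counts in Md and 0 in the other subpopulations. No other cause was tested.

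At an absolute log2 fold change of at least 1 fewer genes pass by construction. The counts became 1577, 806, 573 and 828 for FNP, Mx, Md and PA2 at E10.5, 1635, 861, 626 and 1372 at E11.5, 447 and 773 for PA2 against Md, 6459 for E10.5 against E8.5, 3014 for E11.5 against E10.5, 751, 976, 946 and 923 for Ezh2cKO in FNP, Mx, Md and PA2, 1379 averaged, 4303 for HoxA2OE, 56 for Hoxa2TempMut, 1209 for Control, 12 for genes of PA2 over Md in Hoxa2TempMut and 21 for opposite genes. DESeq2 gave 524 genes whose Ezh2cKO effect differed. With only the groups compared, counts were 1746 for PA2 against Md at E10.5, 3026 for Ezh2cKO in PA2, 6400 for HoxA2OE, 247 for Hoxa2TempMut, 546 for the differing effect and 50 for genes of PA2 over Md in Hoxa2TempMut. Hoxa2TempMut had 215 without the 3 HoxA2OE libraries, and Ezh2cKO averaged 4191 without the E10.5 Mx libraries. For other counts the cause was not tested.

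Replicate numbers were not taken to pair the groups compared, since in no set of groups did every pair of equal number correlate above 0.1. Pairs above it were 6 of 18 within Ezh2cKO, 5 of 18 within wild type at E11.5 and 2 of 11 between E10.5 and E8.5. In Ezh2cKO, Mx and PA2 libraries of equal number did correlate (0.158, 0.129 and 0.214), and Xist matches by number in Mx, Md and PA2. At E11.5, FNP 1, 2 and 3 correlate with Md 2, 1 and 3 (0.233, 0.125 and 0.286) and match in Xist, so libraries of these groups may share embryos, which the fits do not model. In wild type at E10.5, Md and PA2 pairs of equal number lay below 0.1 (0.0697, 0.0532 and 0.0692), but every pair of unequal number was negative. Ddx3y is lowest in replicate 2 and highest in replicate 3 of both. Xist is highest in replicate 2 of both, but replicates 1 and 3 differ in order. Libraries of Md and PA2 at E10.5 may therefore share embryos too. Every library of E8.5 and E10.5 held both Xist (at least 455 CPM) and the Y-linked Ddx3y (at least 9.98 CPM). Each of these libraries thus holds cells of both sexes, from more than 1 embryo. A replicate block kept 1300 named values and ended 41, and gave 2382 for PA2 against Md at E10.5, 819, 6194 and 3133 for Ezh2cKO in FNP, Mx and PA2, 4214 for HoxA2OE, 520 for Hoxa2TempMut, 626 for the differing effect, 65 and 78 for genes of PA2 over Md in HoxA2OE and Hoxa2TempMut, and 101 for opposite genes. Of 212 calls of gene lists, 141 remained with an estimated correlation, and fry gave 321.

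Leaving out single libraries gave 4440 to 5526 calls for FNP at E10.5, 870 to 1549 for Mx, 1031 to 1417 for Md and 1471 to 2196 for PA2. At E11.5 the ranges were 3207 (without FNP replicate 3) to 5353, 1646 to 2404, 1064 to 1473 and 2491 to 3839. PA2 against Md gave 705 to 831 and 1135 to 1619, the stages 13065 to 14060 and 12561 to 13022. Ezh2cKO gave 950 to 1251 in FNP, 722 to 2029 in Mx (also 1400 without Ezh2cKO replicate 2), 1204 to 1580 in Md (lowest without Md replicate 3, 1210 without Ezh2cKO replicate 1), 1229 (without Ezh2cKO replicate 2) to 1719 in PA2, 5373 to 6561 averaged, 270 to 360 for the differing effect and 943 to 1178 for positional sets. HoxA2OE gave 9445 to 11487, Hoxa2TempMut 75 to 130, Control 3320 to 3746, genes of PA2 over Md 104 to 124 and 20 to 31, and opposite genes 44 to 63. Where Mx at E10.5 kept 1 library, it was assumed to vary like the other groups.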

Other observations

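Every test in this part was written before its result was seen. Of the 65 genes opposite in HoxA2OE and Hoxa2TempMut, the share that followed Hoxa2 in Ezh2cKO was counted. If Hoxa2 released in Ezh2cKO FNP and Mx shifts Hoxa2-responsive genes in the gain direction, those called there should move as in HoxA2OE, and 63.265% did. Of those that fall in HoxA2OE, however, 2 fell and 8 rose in FNP, and 1 fell and 7 rose in Mx, so the share comes from genes that rise. If lower Hoxa2 in Ezh2cKO PA2 shifts Hoxa2-responsive genes in the loss direction, those called in PA2 should move as in Hoxa2TempMut, and 67.857% did, with 12 of these from genes that fall in HoxA2OE and 7 from those that rise in it. Neither share reached the level set in advance. Since most genes called in Ezh2cKO rose, neither decides between Hoxa2 and direct release, and both cannot be told apart.

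Other splits of the same libraries were fitted in the same way, in a fit of only the groups compared. For FNP at E10.5, 1 of 100 splits called as many genes (the real one 6533, the highest other 4246), and at E11.5 1 of 100 did for FNP (5231 and 359), Mx (2325 and 367) and PA2 (3629 and 330). For Md and PA2 at E10.5, 2 and 4 of 100 splits called as many as the real 1809 and 2581, with 4098 and 4699 as the highest, and these kept the 3 FNP libraries together. For Md at E11.5, 2 of 100 did (1506 and 2818). The stages gave 1 of 100 each (13486 and 911 for E10.5 against E8.5, 13387 and 2875 for E11.5 against E10.5), as did Ezh2cKO averaged (7081 and 2918). For the differing effect of Ezh2cKO, 2 of 100 did (546 and 1474). With 3 libraries against 3 there are 10 splits, too few to judge. There the real split was the 1 highest each time for PA2 against Md, Ezh2cKO in FNP, Md and PA2, HoxA2OE, Hoxa2TempMut and Control.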
